A study of Mus musculus with 21 samples.

How the data were processed

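RNA sequencing was used to measure gene expression in mice given a control chow or a methionine-restricted (MR) diet. The 21 libraries came from splenic CD8+ T cells (3 control, 3 MR), MC38 tumors (4 control, 4 MR) and BPD6 tumors (4 control, 3 MR). Per the labels' protocols, total RNA was extracted with QIAzol from fresh CD8+ T cells and tumor cells, messenger RNA was captured on poly-T beads, fragmented and primed with random hexamers, and libraries were sequenced on an Illumina platform. Nothing in the labels says whether the kit kept strand, so reads of a gene and of an overlapping antisense gene cannot be told apart here. Poly-T capture ties the reads of partly broken RNA to the 3' end, and the number of reads per gene also grows with transcript length, so values are compared within a gene and between libraries.

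The authors deposited 3 tables, one for each of the CD8+ T cells, MC38 and BPD6. Each table holds estimated counts per gene and library, deposited by the authors without normalization. All values are multiples of 0.5, and 41.0% (CD8), 46.8% (MC38) and 46.6% (BPD6) of them are not whole numbers. The aligner, counter and annotation are not given in the sources used here. The genome build is GRCm38 (mm10) per the submitters' processing notes. Each row carries 1 RefSeq transcript and 1 gene symbol. The tables list 13509 (CD8), 15507 (MC38) and 15184 (BPD6) genes, and every listed gene reaches a count of at least 6 in some library, so genes of very low count had been left out before deposit. The tables also hold the authors' own comparison, with a log2 fold change of MR over control and its standard error, and an unadjusted and an adjusted p-value, per the file headers. Those headers have the column names of a DESeq2 result, but the tool is not named in the labels. The adjusted p-value of the gene of lowest p corresponds to at least 24904 (CD8), 16172 (MC38) and 29463 (BPD6) tests, more than the genes listed. In MC38 the genes of lowest p, Capg and S100a10, share 1 adjusted p-value, so the number of tests there may be well above this bound. A further 21 columns of per-library values were not used here, because their names repeat those of the count columns.

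Columns were matched to samples by name. The BPD6 columns carry another model prefix than the labels, and their MR columns are numbered 1, 2 and 4 while the labels number the MR samples 1 to 3, so the MR columns were matched to their diet group only and the control columns to samples by number. BPD6 replicate numbers in the text are therefore the column numbers. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples, which may be partly technical. No pair of libraries in a group agreed within sampling noise: chi-square per degree of freedom between pairs was at least 12.2.

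The design set edgeR for raw counts and limma on log2 values for any other unit. The deposited values are unnormalized estimated counts, and edgeR was kept after their unit was known. They were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, within each table, with the filterByExpr filter and TMM normalization. Fold changes are log2 of MR over control, ± the standard error (SE). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene passed the test at an adjusted p under 0.05. CPM, counts scaled to a common library size, were computed from the same counts and TMM factors and are given as mean ± SD. The filter left 12348 (CD8), 14034 (MC38) and 13978 (BPD6) genes. The response of the tumor models was compared by the interaction of model and diet over 14257 of the 14422 genes listed in both tumor tables. The tables give a different transcript for some of these genes, and 10548 have the same transcript in both.

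Before the data were examined, 40 gene lists were fixed for T cell states, immune and stromal cell types, other cell types that a sorted fraction or a tumor piece can hold, metabolism, stress responses, interferon responses and antigen presentation. The list of mitochondrially encoded genes had no member in the tables, which left 39 lists. Lists with at least 3 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the 116 tests of the 3 diet comparisons. Camera with an estimated correlation and the rotation test fry were run beside it. For each list the number of members past the test over all genes and the number adjusted over the list alone were counted.

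The genes named were set by a rule made before the data were examined. It takes up to 6 rising and 6 falling genes with the largest change past the test, a mean of at least 1 CPM and no overlap between groups, or the 5 genes of lowest p where none passed. It then takes 3 members of lowest p from each list called by camera, and 12 fixed genes. Clones, predicted genes and antigen receptor segments were left out of the 6 and 6. Not every gene that the rule takes is printed. Genes named outside this rule are said to have been chosen after their values were seen. Coordinates are those of the RefSeq annotation of GRCm38, matched by transcript accession for 13470 (CD8), 15447 (MC38) and 15136 (BPD6) of the listed genes. Transcript lengths are those of the longest GENCODE M21 transcript of a symbol and cover over 98% of the tested genes in each table.

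Library totals were 15733748 to 19562661 (CD8), 16275794 to 24129588 (MC38) and 18346332 to 20836084 (BPD6) counts. The procedure was tested on simulated data with 200 changed genes per comparison, 50 at each of 4 sizes. For CD8 (12348 genes) it recovered 20% of the 1.5-fold changes, 64% at 2-fold, 84% at 3-fold and 90% at 4-fold. The corresponding shares were 14%, 64%, 68% and 90% for MC38 (14034 genes), 8%, 52%, 80% and 90% for BPD6 (13978 genes), and 4%, 42%, 64% and 82% for the interaction (14257 genes). Unchanged genes made up 3.73%, 6.35%, 4.17% and 5.88% of the calls. In simulated tables with a list shifted 1.3-fold, camera with the preset correlation called the list in each comparison and 0 (CD8), 0 (MC38) and 1 (BPD6) of the other lists. The unadjusted camera p of the shifted list was 1.86e-15, 3.54e-12 and 5.83e-11 with the preset correlation. With an estimated correlation it was 0.000953, 0.000266 and 0.00778, and 0 other lists were called. The estimated correlation is thus far less sensitive, and a call lost with it can still be a true shift. Genes were drawn independently in the simulations, from the fitted dispersions and without variation shared by many genes of a library. The shares recovered hold for that setting with 200 changed genes, and those in the real libraries may be lower. The simulations also cannot show how often the preset correlation calls unchanged lists whose genes move together, as in real libraries.

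Alternatives set before the data were examined were DESeq2 1.42.0, median-of-ratios size factors in edgeR, no filter on low counts, limma-voom, a minimum absolute log2 fold change of 1, the replicate number as a block, and leaving out each library in turn. After the data had been seen, corrections for transcript length and covariates of marker scores were added, along with the genes having the same transcript in both tumor tables and a joint fit at an unadjusted p of 0.05. Figures were drawn with matplotlib 3.10.9.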

Results

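The data set described the transcriptome of mice fed a control chow or a methionine-restricted diet, in 3 materials. CD8+ T cells, the cytotoxic arm of the T cell response, were taken from the spleen, with 3 control and 3 MR libraries. MC38, a mouse colon carcinoma line, was grown as tumors, with 4 control and 4 MR libraries. BPD6, a mouse melanoma line, was grown as tumors, with 4 control and 3 MR libraries. The series title sets these samples in a study of T cell metabolism, activation and tumor growth under methionine restriction. Counts per library totalled 15739076 to 19562661 for control and 15733748 to 16361594 for MR CD8+ T cells. They were 16275794 to 18521831 and 16536287 to 24129588 for MC38, and 18346332 to 18967182 and 18399173 to 20836084 for BPD6.

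In splenic CD8+ T cells, MR was accompanied by lower expression of interferon-stimulated and proliferation genes, and by higher expression of genes including Capn11, Syt6, Trnp1 and Zc3h6. Of 26 measured type I interferon genes, 24 were lower with MR (median log2 fold change -0.84, or -0.47 without control replicate 1), and Oas2, Oas3 and Bst2 were among the 6 that passed the test. Of 27 proliferation genes, 23 were lower (median -0.48), and Birc5, Rrm2, Cdk1 and Mki67 fell. All 14 list calls were lost with an estimated correlation (adjusted p = 0.452 to 0.782 with an estimated correlation). Of 10 splits of these libraries, the diet split included, 2 called at least 14 lists. Genes listed as markers of other cells were lower in the same libraries, with medians of -1.26 (red cell), -1.01 (B cell), -0.61 (dendritic cell) and -0.55 (NK cell), the last 3 at -0.39, -0.33 and -0.35 without control replicate 3. In all, 73 genes rose and 101 fell among 12348 tested (edgeR quasi-likelihood test, adjusted p under 0.05, n = 3 against 3). All 174 had groups that did not overlap, as did 22.4% of all tested genes, where chance gives 10%.

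Among the genes that rose, Trnp1, which encodes a nuclear protein (chromosome 4, 133491097 to 133499645, transcript NM_001081156), went from 36.9 ± 11.8 CPM in control to 196 ± 52.8 CPM in MR cells (SD, n = 3 each). Its log2 fold change was 2.41 ± 0.23 (SE), with an edgeR adjusted p of 0.000309, the lowest of the table. Syt6, a synaptotagmin gene (chromosome 3, 103575245 to 103645567, NM_001276681), rose from 9.003 ± 5.01 to 59.5 ± 23.7 CPM, a log2 change of 2.71 ± 0.33 (edgeR adjusted p = 0.00143). Zc3h6, a zinc finger gene (chromosome 2, 128967402 to 129018563, NM_178404), rose from 4.86 ± 0.15 to 22.8 ± 9.83 CPM, by 2.23 ± 0.29 (edgeR adjusted p = 0.00195). Capn11, of the calpain protease family (chromosome 17, 45630191 to 45659709), had the largest rise, from 0.22 ± 0.38 to 5.01 ± 3.12 CPM, with a log2 change of 4.44 ± 0.89 (edgeR adjusted p = 0.0276). DESeq2 did not call Capn11. Tubb3, a beta tubulin gene, rose by 2.12 ± 0.35 and Ctse, encoding cathepsin E, by 1.99 ± 0.43.

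Among the genes that fell, Vwce (chromosome 19, 10634218 to 10666213, NM_027913) went from 3.42 ± 1.57 to 0.082 ± 0.091 CPM, a log2 change of -5.28 ± 0.83 (edgeR adjusted p = 0.00971). Scx, encoding the tendon transcription factor scleraxis, changed by -2.96 ± 0.65 and stayed near 2 CPM or under in both groups (2.09 ± 0.36 and 0.26 ± 0.087 CPM). Lbp, encoding lipopolysaccharide-binding protein (chromosome 2, 158306493 to 158332852), changed by -2.18 ± 0.36, from 10.3 ± 3.55 to 2.26 ± 0.69 CPM (edgeR adjusted p = 0.0125). The mitotic spindle gene Spag5 changed by -2.08 ± 0.43, the cell cycle kinase gene Cdk1 by -1.89 ± 0.44 and Rab44, of the Rab GTPase family, by -1.87 ± 0.38. Of the 23 genes named by rule that passed the test, Trnp1, Syt6 and Zc3h6 were called under the alternatives that were run for single genes.

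**Figure D1:**
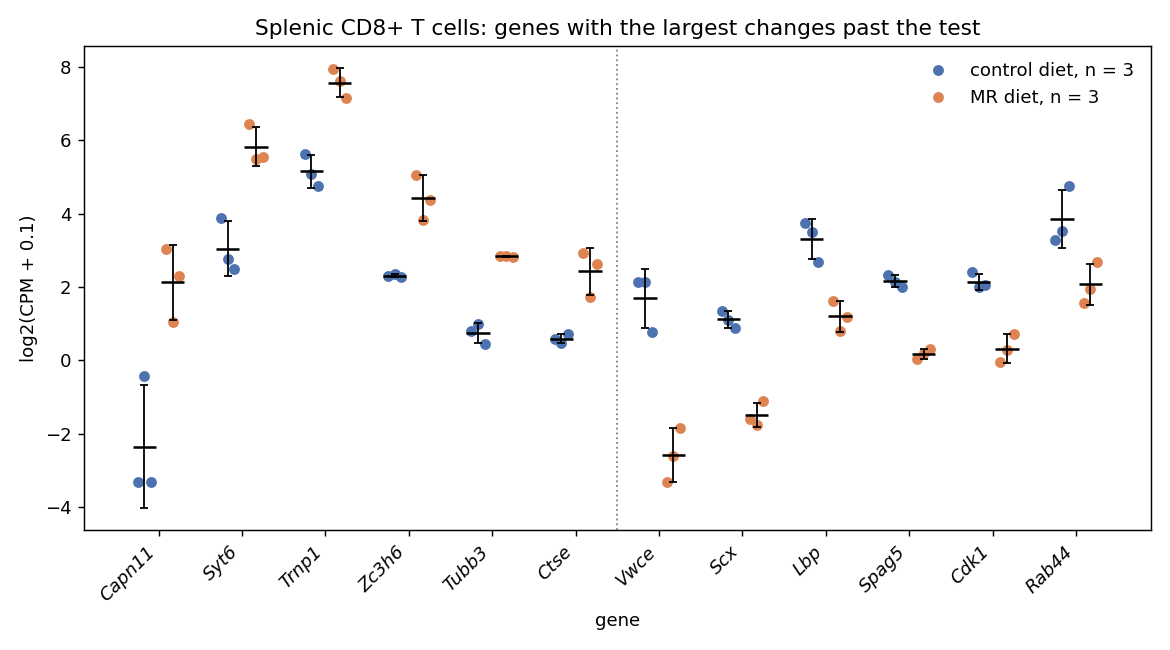
Expression of the 12 genes with the largest changes past the test in splenic CD8+ T cells, as log2(CPM + 0.1) for each library (points), with the group mean (horizontal line) and SD (error bar), n = 3 per diet. The 6 genes left of the dotted line rose with MR and the 6 to its right fell, and the groups of each gene do not overlap.

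The type I interferon list, genes induced by interferon alpha and beta, had the lowest p of the lists in CD8+ T cells (camera adjusted p = 5.60e-12). With an estimated correlation the call was lost (adjusted p = 0.682 with an estimated correlation). Adjusted over the list alone, 18 of its 26 members fell, beside 6 over all genes. Oas2, an antiviral oligoadenylate synthetase, went from 47.6 ± 24.6 to 17.2 ± 4.51 CPM (log2 fold change -1.47 ± 0.29, edgeR adjusted p = 0.0254). Oas3 changed by -0.94 ± 0.20 and Bst2, encoding tetherin, by -0.98 ± 0.17. Isg15 (-1.27) and Ifit1 (-1.02) also fell and were chosen after their values were seen. Without control replicate 1 the list median was -0.47, against -0.84 with all libraries. B cell, dendritic cell and NK cell markers were lower in the same libraries (medians -1.01, -0.61 and -0.55).

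The list of interferon gamma response and chemokine genes was lower in 15 of 16 members (median -0.50, camera adjusted p = 1.82e-05, adjusted p = 0.682 with an estimated correlation). Its guanylate-binding protein gene Gbp3 fell (log2 fold change -0.88 ± 0.20), 1 member over all genes and 5 adjusted over the list alone. Irgm2 (-0.73) and Ifi47 (-0.52) did not pass, and the list median was -0.32 without control replicate 2. The MHC class I list was lower in 12 of 15 members (median -0.20, camera adjusted p = 0.0150, adjusted p = 0.682 with an estimated correlation), with 0 members past edgeR over all genes and 1 adjusted over the list alone. Its call was lost without control replicate 1 (camera adjusted p = 0.0773) or 2 (0.0868). Psmb10, an immunoproteasome subunit gene, had a log2 fold change of -0.57 ± 0.16, Psme2 of -0.36 and Psmb9 of -0.29, none past the test. Cd274, encoding PD-L1, was 35.0 ± 1.43 CPM in control and 29.2 ± 1.71 CPM in MR cells (edgeR adjusted p = 0.407).

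Cytotoxic effector genes were lower in 23 of 26 members (median -0.61, camera adjusted p = 2.12e-07, adjusted p = 0.558 with an estimated correlation). None passed edgeR over all genes, and 11 did adjusted over the list alone. The lowest p-values belonged to Tbx21, encoding the transcription factor T-bet (-0.59 ± 0.15), Cx3cr1, a chemokine receptor gene of effector cells (-1.23 ± 0.33), and Id2 (-0.58 ± 0.16). Of the fixed effector genes, Gzmb, encoding granzyme B, had a log2 fold change of -0.53 ± 0.31 (edgeR adjusted p = 0.409). Prf1, encoding perforin, stood at -0.09 ± 0.18 (edgeR adjusted p = 0.828), and Ifng at -0.94 ± 0.50 with 3.90 ± 1.86 against 2.03 ± 1.004 CPM. NK cells also express Tbx21, Cx3cr1, Gzmb and Prf1, and NK cell genes were lower in the same MR libraries (12 of 12 members, median -0.55, Klre1 at -1.44). T cell activation genes were lower in 20 of 24 members (median -0.34, camera adjusted p = 0.000139, adjusted p = 0.558 with an estimated correlation), 0 over all genes and 6 adjusted over the list alone. They included Fosl2 (-0.67), Irf8 (-0.72) and Batf (-0.59), none past edgeR, and the median was -0.54 without MR replicate 3. The inhibitory receptor gene Pdcd1 was near 1 CPM in both groups (0.98 ± 0.76 and 0.93 ± 0.52), and the checkpoint list did not pass (5 of 12 members higher, camera adjusted p = 0.659).

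Proliferation genes passed the list test (camera adjusted p = 6.40e-06, adjusted p = 0.558 with an estimated correlation), with 4 members down over all genes and 6 adjusted over the list alone. Birc5, encoding survivin, went from 12 ± 1.41 to 3.86 ± 1.06 CPM (log2 fold change -1.63 ± 0.29, edgeR adjusted p = 0.0152). Rrm2, a ribonucleotide reductase subunit gene, changed by -1.64 ± 0.34 and Mki67, encoding the proliferation antigen Ki-67, by -1.24 ± 0.26 (41.7 ± 9.99 to 17.6 ± 7.06 CPM). The immediate-early and stress list was lower in 16 of 16 members (median -0.35, camera adjusted p = 2.54e-05, adjusted p = 0.452 with an estimated correlation), with 1 down over all genes and 4 adjusted over the list alone. Its chaperone gene Hsph1 fell by 1.76 on the log2 scale, while Hspa8 (-0.64) and Nr4a1 (-0.55) did not pass. Markers of B cells and of NK cells were lower in the same libraries (medians -1.01 and -0.55).

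The unfolded protein response list was lower in 13 of 18 members (median -0.27, camera adjusted p = 0.00152, adjusted p = 0.558 with an estimated correlation), with 2 down both over all genes and adjusted over the list alone. The endoplasmic reticulum chaperone genes Hsp90b1 (458.6 ± 28.9 to 249.5 ± 36.7 CPM, log2 fold change -0.88 ± 0.16) and Pdia6 (-0.68 ± 0.16) fell, and Edem1 (-0.43) did not pass. Among genes chosen after their values were seen, the cold-inducible RNA-binding protein genes Cirbp (1.45 ± 0.19) and Rbm3 (1.09 ± 0.17) rose. So did the anti-apoptotic gene Bcl2 (0.75), the clock gene Per2 (0.99) and the glucocorticoid target Fkbp5 (1.11). The co-chaperone genes Chordc1 (-1.12) and Stip1 (-1.05) fell.

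Genes listed as markers of other cells also stood lower in the MR libraries. The NK cell list shares Eomes with the naive and memory T cell list and Gzma with the cytotoxic list. Fewer NK cells therefore cannot be told apart here from a change within the CD8+ T cells. B cell markers were lower in 13 of 14 members (median -1.01, camera adjusted p = 0.0208, adjusted p = 0.782 with an estimated correlation), with 0 members past edgeR over all genes or adjusted over the list alone. The spread between control libraries was wide: Pax5 was 63.5 ± 58.0 against 23.2 ± 9.79 CPM. The B cell call was lost without control replicate 1 (camera adjusted p = 0.142), control replicate 3 (0.305, median -0.39) or MR replicate 3 (0.202). NK cell genes were lower in 12 of 12 members (median -0.55, camera adjusted p = 0.000110, adjusted p = 0.682 with an estimated correlation), with 1 down over all genes, the receptor gene Klre1 (-1.44 ± 0.30), and 6 adjusted over the list alone. Eomes (-0.73) and Klra8 (-0.78), whose family shares reads, did not pass. The NK median was -0.35 without control replicate 3 and -0.88 without MR replicate 2. Dendritic cell genes were lower in 9 of 10 (median -0.61, camera adjusted p = 0.0145, adjusted p = 0.682 with an estimated correlation), including Cd83 (-0.98), Itgax (-0.60) and Xcr1 (-1.73), none past edgeR and 1 adjusted over the list alone, with a median of -0.33 without control replicate 3.

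Red cell genes were lower in 3 of 4 members (median -1.26, camera adjusted p = 0.0194, adjusted p = 0.682 with an estimated correlation). None passed edgeR over all genes and 3 did adjusted over the list alone. The hemoglobin genes Hbb-bs (-1.75), Hba-a1 (-1.24) and Hba-a2 (-1.27) are uncertain singly, because Hba-a1 and Hba-a2 are near-identical copies that share reads, and the list's call was lost without MR replicate 3 (camera adjusted p = 0.0684). The CD4 and regulatory T cell list was lower in 7 of 7 members (median -0.47, camera adjusted p = 0.0283, adjusted p = 0.682 with an estimated correlation), 0 over all genes and 1 adjusted over the list alone. Foxp3 was 109 ± 13.5 CPM in control and 68.3 ± 22.5 CPM in MR cells, beside Ikzf2 (-0.50) and Ctla4 (-0.64), and the list's call was lost without control replicate 1 (camera adjusted p = 0.0722, median -0.30) or MR replicate 1 (0.0508). Cd4 was 3.0 ± 1.44 and 2.96 ± 1.302 CPM in control and MR cells, so the lower Foxp3 did not come with lower Cd4. The T cell list itself did not pass (7 of 13 members higher, camera adjusted p = 0.678), and Cd8a was 1501 ± 176 and 1361 ± 153 CPM (edgeR adjusted p = 0.712). Macrophage genes did not pass as a list (camera adjusted p = 0.417), but their member Lyz2, encoding lysozyme, fell (-1.304 ± 0.30).

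Lipid and sterol synthesis was the list called upward in CD8+ T cells, with 17 of 24 members higher (median 0.20, camera adjusted p = 0.0434, adjusted p = 0.713 with an estimated correlation). None of its members passed edgeR over all genes or adjusted over the list alone. The fatty acid synthase gene Fasn had a log2 fold change of 0.42 ± 0.19. The call was lost without control replicate 2 (camera adjusted p = 0.128), MR replicate 1 (0.169) or MR replicate 2 (0.153). Methionine and one-carbon genes were higher in 15 of 25 members (median 0.12, camera adjusted p = 0.302), and Mat2a, which encodes the enzyme making S-adenosylmethionine, stood at -0.34 ± 0.19 (edgeR adjusted p = 0.376). Amino acid transporters (median 0.18, camera adjusted p = 0.477), ATF4 target genes (0.04, 0.518), nuclear OXPHOS genes (-0.02, 0.508), glycolysis genes (0.12, 0.340) and naive and memory T cell genes (0.10, 0.518, with Bcl2 the 1 member up over all genes) did not pass. Atf4 (-0.23), Myc (-0.10) and the transporter gene Slc7a5 (0.20) did not pass either. The 24 lists that did not pass had camera adjusted p of 0.126 to 0.945.

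The authors' deposited table gives 580 genes at an adjusted p under 0.05 in CD8+ T cells, 266 up and 314 down, and 173 of the 174 edgeR calls were among them. The count depended on single libraries: edgeR called 7 genes without MR replicate 1, 36 without control replicate 1 and 290 without MR replicate 2. DESeq2 called 559.

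In MC38 tumors, MR was accompanied by higher expression of macrophage, MHC class II and fat cell genes and of genes for the ribosome and for oxidative phosphorylation, seen as groups and not in single genes past the test. Of 35 splits of these libraries, the diet split included, 26 called at least 13 lists, so chance was not excluded for these groups. All 13 list calls were lost with an estimated correlation (adjusted p = 0.480 to 0.786 with an estimated correlation), and a length correction chosen after seeing the data brought the OXPHOS, ribosomal protein and methyltransferase medians to 0.13, 0.10 and -0.06. Without MR replicate 1 the OXPHOS and ribosomal protein medians were 0.22 and 0.12. All 21 measured macrophage and monocyte genes and all 9 MHC class II genes were higher with MR (medians 0.56 and 1.296), as were 81 of 81 ribosomal protein genes and 69 of 72 nuclear OXPHOS genes (medians 0.32 and 0.35). Methyltransferase genes were lower in 23 of 24 (median -0.17). No gene of 14034 passed the edgeR quasi-likelihood test (n = 4 against 4, lowest adjusted p 0.243), with 1981 genes at an unadjusted p under 0.05. That count is above the 5% of tested genes that chance gives, but a split of these libraries other than by diet gave 3069. DESeq2 called 406 genes and limma-voom 0, and the authors' deposited table gives 353. Without control replicate 1 the count at an unadjusted p under 0.05 was 1111.

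The 5 genes of lowest p, none past edgeR, did not overlap between diets. S100a10, encoding the partner of annexin A2 (chromosome 3, 93555117 to 93564645), was 246.5 ± 16.6 CPM in control and 380.3 ± 26.0 CPM in MR tumors (SD, n = 4 each), a log2 fold change of 0.63 ± 0.09 (edgeR adjusted p = 0.243). Capg, an actin capping gene (chromosome 6, 72538282 to 72562983), was 130.3 ± 5.80 and 181 ± 6.14 CPM (0.47 ± 0.07). Gpsm3, a G protein signalling modulator gene, had a log2 fold change of 0.71 ± 0.11. Nsd2, a histone methyltransferase gene, stood at -0.75 ± 0.11 and Arhgef28 at -0.65 ± 0.10. In the authors' deposited table these 5 have adjusted p of 4.28e-10 (S100a10 and Capg), 2.73e-05 (Gpsm3), 4.76e-06 (Nsd2) and 1.90e-06 (Arhgef28). The values of these genes carry no correction for the trend with transcript length given below.

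The macrophage and monocyte list passed camera (adjusted p = 4.22e-06, adjusted p = 0.682 with an estimated correlation), with 0 members past edgeR over all genes and 7 adjusted over the list alone. Apoe, encoding a lipid carrier that macrophages make, was 275 ± 120 CPM in control and 850 ± 435 CPM in MR tumors (1.63 ± 0.46). Trem2, a lipid-sensing receptor gene, was 10.9 ± 2.95 and 22.2 ± 5.99 CPM (1.03 ± 0.25), and the Fc receptor gene Fcgr3 stood at 1.02 ± 0.29. For MHC class II genes (camera adjusted p = 4.95e-05, adjusted p = 0.682 with an estimated correlation), 0 passed over all genes and 7 adjusted over the list alone. Their examples were Ctss (0.94 ± 0.24), H2-Eb1 (1.51 ± 0.53) and H2-DMb2 (3.20 ± 1.10). MR replicate 3 had 26.8 CPM of H2-DMb2 and the other MR libraries 1.33 to 2.35 CPM, and the class II median without this library was 0.88.

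Fat cell genes moved with the macrophage genes: 9 of 9 were higher with MR (median 2.69, camera adjusted p = 0.00215, adjusted p = 0.682 with an estimated correlation), 0 over all genes and 6 adjusted over the list alone. Adipoq, encoding adiponectin, was 9.44, 25.7, 18.1 and 0.24 CPM in MR replicates 1 to 4 and 0.16 to 2.51 CPM in the control libraries. Retn, encoding resistin, had a log2 fold change of 4.10 ± 1.24, Cidec of 3.12 ± 0.94 and Fabp4 of 2.15 ± 0.65. MR replicate 4, with the lowest Adipoq of the MR libraries, also had the lowest Apoe and Trem2 of them (370.8 and 16.5 CPM).

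T cell genes were higher in 12 of 13 members (median 1.02, camera adjusted p = 0.00838, adjusted p = 0.754 with an estimated correlation), with 0 past edgeR over all genes or adjusted over the list alone. Cd3d, a T cell receptor complex gene, was 1.997 ± 0.56 and 5.52 ± 2.85 CPM, Cd3g stood at 1.28 and Cd8b1 at 1.15. Cd8a was 4.58 ± 1.35 and 9.30 ± 6.15 CPM (edgeR adjusted p = 0.365). Without MR replicate 3 the T cell median was 0.54 and the call was lost (camera adjusted p = 0.0653). The cytotoxic list did not pass (median 0.22, camera adjusted p = 0.333), Gzmb was at -0.26 ± 0.36, Prf1 at -0.70 ± 0.44 and Ifng at 0.18 ± 0.52. Checkpoint genes were higher in 12 of 12 (median 0.46, camera adjusted p = 0.0387, adjusted p = 0.766 with an estimated correlation), among them Lag3 (0.45), Entpd1 (0.64) and Tox (1.35), with 0 past edgeR in either count. Without MR replicate 1 their median was 0.72, and the call was lost without control replicate 2 or 3 (camera adjusted p = 0.0676 and 0.164) and without MR replicate 2, 3 or 4 (0.133, 0.283 and 0.197). Pdcd1 had a log2 fold change of 0.58 and Cd274 of -0.10.

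MHC class I genes were higher in 13 of 15 members (median 0.29, camera adjusted p = 4.95e-05, adjusted p = 0.682 with an estimated correlation), 0 over all genes and 8 adjusted over the list alone. B2m, the light chain of MHC class I, was 2138 ± 100 and 2647 ± 118 CPM (0.31 ± 0.08), and the immunoproteasome genes Psmb9 and Psmb8 stood at 0.45 and 0.36. Interferon gamma response genes were higher in 16 of 18 (median 0.22, camera adjusted p = 0.0108, adjusted p = 0.682 with an estimated correlation), with Ifi47 (0.36), Irf1 (0.27) and Igtp (0.32), 0 past edgeR in either count. This call was lost without control replicate 2 or 3 (camera adjusted p = 0.0907 and 0.0561) or MR replicate 4 (0.0576). Dendritic cell genes were higher in 10 of 12 (median 0.65, camera adjusted p = 0.00913, adjusted p = 0.682 with an estimated correlation), with Clec10a (1.07), Cd209a (1.80) and Xcr1 (0.64) and 0 past edgeR in either count. Without MR replicate 3 their median was 0.42. None of the lists in this paragraph was refitted with the length correction given below.

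Nuclear OXPHOS genes had the lowest list p of the 3 materials (camera adjusted p = 2.16e-18, adjusted p = 0.682 with an estimated correlation), with 0 members past edgeR over all genes and 13 adjusted over the list alone. Ndufa11, of respiratory complex I, had a log2 fold change of 0.48 ± 0.11, Uqcrh, of complex III, of 0.59 ± 0.14 and Atp5mpl, of ATP synthase, of 0.62 ± 0.15. Ribosomal protein genes passed likewise (camera adjusted p = 5.60e-12, adjusted p = 0.748 with an estimated correlation), with Rpl39 (0.44), Rps29 (0.81) and Rpl37a (0.63) and 0 past edgeR in either count. The methyltransferase list was called lower (camera adjusted p = 4.49e-05, adjusted p = 0.480 with an estimated correlation), with Dnmt3b (-0.47), Carm1 (-0.25) and Dot1l (-0.38) and 0 past edgeR in either count. These groups moved with transcript length. OXPHOS and ribosomal protein genes have median transcript lengths of 1003 and 1076 bases, methyltransferase genes of 5912 bases. Across 13835 genes, which are not independent replicates, the MC38 fold change fell with transcript length (Spearman -0.43). Per library the correlation was 0.23 ± 0.15 in control and -0.15 ± 0.24 in MR tumors (SD, n = 4 each, exact permutation test, two-sided p = 0.086). This trend runs over all genes. Length-corrected medians were computed in MC38 only for these groups and for macrophage and MHC class II genes, not for other lists or single genes. After a length correction per library, chosen after seeing the data, the medians were 0.13 (OXPHOS), 0.10 (ribosomal protein) and -0.06 (methyltransferase). With the fat cell marker score as a covariate, also chosen after seeing the data, they were 0.20, 0.13 and -0.14. Without MR replicate 1 the OXPHOS and ribosomal protein medians were 0.22 and 0.12.

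**Figure D2:**
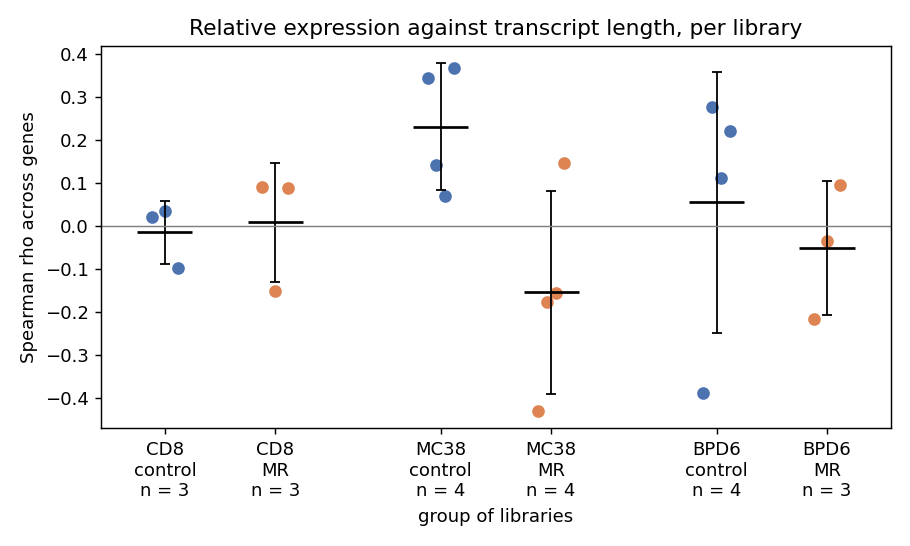
Spearman correlation across genes between relative expression in a library and transcript length (points, 1 per library), with group mean (line) and SD (error bar), for 3 materials and both diets. MC38 control libraries lie between 0.071 and 0.368 and MC38 MR libraries between -0.429 and 0.147.

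ATF4 target genes, the integrated stress response to amino acid shortage, were lower in 22 of 28 members in MC38 (median -0.12, camera adjusted p = 0.0107, adjusted p = 0.786 with an estimated correlation), 0 over all genes and 1 adjusted over the list alone. Sesn2, encoding a leucine sensor, was 64.3 ± 8.26 and 42.5 ± 4.14 CPM (-0.60 ± 0.11), Chac1 stood at -0.70 ± 0.20 and Aldh18a1 at -0.32. Without MR replicate 1 this median was -0.26, and the call was lost without control replicate 3 (camera adjusted p = 0.218, median -0.01), MR replicate 2 (0.203, median -0.06) or MR replicate 4 (0.191, median -0.07). The ATF4 median was -0.20 without control replicate 4. Asns (-0.06), Atf4 (0.01) and Mat2a (-0.14) did not pass, and the amino acid transporter gene Slc7a5 was 792 ± 119 and 593 ± 74.2 CPM (-0.42 ± 0.13, edgeR adjusted p = 0.269). Fatty acid oxidation genes were higher in 14 of 16 (median 0.13, camera adjusted p = 0.0120, adjusted p = 0.682 with an estimated correlation), with Acaa2 (0.29), Slc25a20 (0.31) and Acadl (0.17) and 0 past edgeR in either count, and lost their call without MR replicate 2 (camera adjusted p = 0.0703). Proliferation genes did not pass (median 0.01, camera adjusted p = 0.477), nor did type I interferon genes, whose median of 0.04 was positive while camera pointed down (adjusted p = 0.644). Methionine and one-carbon genes did not pass (median -0.08, camera adjusted p = 0.127), nor did Mki67 (-0.16) or Myc (-0.12). The 26 lists that did not pass had camera adjusted p of 0.0522 to 0.957.

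In BPD6 tumors, MR was accompanied by higher type I interferon, hypoxia and immediate-early genes and lower proliferation genes as groups, while no single gene passed the test. Of 35 splits of these libraries, the diet split included, 5 called at least as many lists as diet (23, adjusted within the comparison). Chance was therefore not excluded for these groups. All 21 list calls were lost with an estimated correlation (adjusted p = 0.169 to 0.832 with an estimated correlation), and the hypoxia median was 0.19 without MR replicate 1, 0.89 without control replicate 3 and 0.26 without control replicate 4. The type I interferon median was 0.44 without control replicate 4, and the proliferation median -0.10 without control replicate 1 and -0.11 without MR replicate 4. All 26 type I interferon genes were higher with MR (median 0.66), as were 15 of 16 hypoxia genes (0.48) and 14 of 18 immediate-early and stress genes (0.32), and all 27 proliferation genes were lower (-0.19). The edgeR quasi-likelihood test called 0 of 13978 genes (n = 4 against 3, lowest adjusted p 0.9997), with 258 at an unadjusted p under 0.05. That count is under the 5% of tested genes that chance gives. DESeq2 and the authors' deposited table each called 1, Atf3, a stress-response transcription factor gene, and limma-voom 0. The count at an unadjusted p under 0.05 was 110 without MR replicate 1, 514 without MR replicate 2, 463 without control replicate 3 and 396 without control replicate 1.

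Atf3 (chromosome 1, 191170296 to 191183333, NM_007498) was 11.8 ± 2.09 CPM in control (n = 4) and 23.8 ± 1.75 CPM in MR tumors (n = 3), a log2 fold change of 1.01 ± 0.16 (SE). The next genes by p, none past edgeR, were the inflammatory caspase gene Casp4 (0.70 ± 0.13), the heparanase gene Hpse (0.79 ± 0.17), the acid phosphatase gene Acp5 (-0.91 ± 0.20) and Fosb (0.76 ± 0.17). The immediate-early list passed camera (adjusted p = 9.75e-08, adjusted p = 0.169 with an estimated correlation) and was the list that fry called (adjusted p = 0.0220). None of its members passed over all genes and 5 did adjusted over the list alone. Fos was 11.7 ± 2.72 and 25.7 ± 9.85 CPM (1.14 ± 0.29). T cell activation genes, which share Fos, Egr1 and Nr4a1 with that list, were higher in 18 of 24 (median 0.24, camera adjusted p = 0.000492, adjusted p = 0.558 with an estimated correlation), with Junb (0.32) and Nr4a1 (0.79) and 0 past edgeR in either count. Their median was 0.10 without MR replicate 1 and 0.16 without control replicate 1.

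For the type I interferon list (camera adjusted p = 6.12e-17, adjusted p = 0.682 with an estimated correlation), 0 members passed edgeR over all genes or adjusted over the list alone. Ifit2 was 60.03 ± 11.1 and 91.4 ± 7.42 CPM (0.61 ± 0.15), Rsad2, encoding viperin, 22.5 ± 9.60 and 45.3 ± 10.6 CPM (1.01 ± 0.35), and Ifit3 48.7 ± 25.9 and 108.5 ± 37.2 CPM (1.15 ± 0.48). Without control replicate 4 the median was 0.44. The interferon gamma response list was higher in 15 of 18 (median 0.40, camera adjusted p = 0.00353, adjusted p = 0.766 with an estimated correlation) with 0 past edgeR in either count. Cd274 was 19.7 ± 6.34 and 37.1 ± 12.4 CPM (0.91 ± 0.30), Socs1 stood at 0.31 and Irgm2 at 0.51. MHC class I genes were higher in 15 of 15 (median 0.33, camera adjusted p = 0.000275, adjusted p = 0.748 with an estimated correlation), 0 past edgeR in either count, with B2m at 0.34, H2-T23 at 0.68 and H2-D1 at 0.33. H2-D1 and H2-T23 have close relatives and may share reads with them. Control replicate 4 stood apart in these genes, with 1311 CPM of B2m against 1842 CPM in the nearest control library. Without MR replicate 1 the medians were 0.09 (interferon gamma) and 0.10 (MHC class I), without control replicate 4 they were 0.13 and 0.11, and without MR replicate 4 they were 0.73 and 0.52. Without control replicate 4 the interferon gamma call was lost (camera adjusted p = 0.957) and pointed down. That call was also lost without MR replicate 1 (0.329) or 2 (0.152), and the MHC class I call without control replicate 4 (0.306) or MR replicate 1 (0.114).

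T cell genes were higher in 11 of 11 in BPD6 tumors (median 0.35, camera adjusted p = 0.0219, adjusted p = 0.761 with an estimated correlation), at low levels: Cd3d was 0.98 ± 0.67 and 1.503 ± 0.97 CPM, Cd8b1 0.87 ± 0.83 and 1.46 ± 0.62 CPM, and Cd6 0.47 ± 0.53 and 0.99 ± 0.27 CPM. The cytotoxic list was higher in 17 of 19 (median 0.18, camera adjusted p = 0.0150, adjusted p = 0.748 with an estimated correlation), with Ccl4 (1.28 ± 0.41), Lamp1 (0.18) and Ccl3 (0.97 ± 0.55). Ccl3 and Ccl4 overlap on chromosome 11 and are uncertain singly. Without MR replicate 1 both medians turned, to -0.08 (T cell) and -0.15 (cytotoxic). The T cell median was 0.10 without control replicate 4, 0.54 without control replicate 3 and 0.70 without control replicate 2 or MR replicate 4. The cytotoxic median was 0.02 without control replicate 4, 0.33 without control replicate 1 or MR replicate 2, 0.34 without control replicate 3 and 0.48 without MR replicate 4. Gzmb (0.29), Prf1 (0.15), Pdcd1 (-0.12) and Cd8a (0.45) did not pass. Macrophage genes were higher in 19 of 22 (median 0.15, camera adjusted p = 0.000312, adjusted p = 0.682 with an estimated correlation), with Cd68 (0.37 ± 0.09) and Adgre1 (0.30), and their median was 0.02 without MR replicate 2, 0.28 without control replicate 2 and 0.30 without MR replicate 4. B cell genes were higher in 5 of 5 (median 0.22, camera adjusted p = 0.0376, adjusted p = 0.645 with an estimated correlation), with Ebf1 (0.38), Cd22 (0.48) and Blnk (0.19). Naive and memory T cell genes were higher in 12 of 16 (median 0.13, camera adjusted p = 0.0251, adjusted p = 0.558 with an estimated correlation), with S1pr1 (0.40) and Klf2 (0.53), which endothelial cells also express, and Eomes (-0.51). In these 5 lists 0 members passed edgeR over all genes or adjusted over the list alone. The T cell call was lost without control replicate 1 or 4 (camera adjusted p = 0.108 and 0.886) or MR replicate 1 or 2 (0.654 and 0.0926), and the cytotoxic call without control replicate 4 (0.589) or MR replicate 1 or 2 (0.531 and 0.0870). The macrophage call was lost without MR replicate 2 (0.327), the B cell call without control replicate 3 (0.198, median 0.10) or MR replicate 2 (0.342), and the naive and memory call without control replicate 1 (0.439, median 0.08) or MR replicate 2 (0.200, median 0.24). Without control replicate 2 the medians were 0.34 (B cell) and 0.25 (naive and memory), and the latter was 0.23 without control replicate 3.

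Hypoxia genes (camera adjusted p = 5.48e-06, adjusted p = 0.682 with an estimated correlation) included Ndrg1 (0.73 ± 0.30), the glucose transporter gene Slc2a1 (0.53 ± 0.33) and Adm (0.90 ± 0.59). Glycolysis genes were higher in 19 of 21 (median 0.25, camera adjusted p = 0.000157, adjusted p = 0.682 with an estimated correlation), with Eno2 (0.50), Hk2 (0.32) and Slc2a3 (0.77), and the call was lost without MR replicate 1 (camera adjusted p = 0.0620, median 0.03). The glycolysis median was 0.14, 0.47 and 0.11 without control replicates 2, 3 and 4. ATF4 target genes were higher in 23 of 29 (median 0.10, camera adjusted p = 0.00118, adjusted p = 0.748 with an estimated correlation), with Atf3, Cebpb (0.35) and Ddit3, encoding CHOP (0.63), and 1 past edgeR adjusted over the list alone. This call was lost without control replicate 3 (camera adjusted p = 0.0890, median 0.05) or MR replicate 4 (0.574, median -0.04), and the median was 0.19 without MR replicate 1. Ribosomal protein genes were higher in 80 of 83 (median 0.13, camera adjusted p = 2.57e-10, adjusted p = 0.748 with an estimated correlation), with Rps21 (0.26) higher and Rpl7l1 (-0.23) lower, and a median of 0.07, 0.20 and 0.08 without MR replicates 1, 2 and 4 and 0.20 without control replicate 1. Apart from the ATF4 member, 0 members of these lists passed edgeR in either count. Asns (0.01), Atf4 (0.10), Mat2a (-0.01), Slc7a5 (0.00) and Myc (0.00) did not pass.

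Proliferation genes in BPD6 (camera adjusted p = 1.91e-07, adjusted p = 0.685 with an estimated correlation) included Mki67 (198 ± 33.7 and 162 ± 16.0 CPM, -0.29 ± 0.15), Ccnb1 (-0.23) and Cenpf (-0.17), and their median was -0.10 without control replicate 1 and -0.11 without MR replicate 4. Ribosome biogenesis genes were lower in 19 of 20 (median -0.11, camera adjusted p = 1.71e-05, adjusted p = 0.682 with an estimated correlation), with Polr1b (-0.28), Dkc1 (-0.30) and Wdr12 (-0.27), and a median of -0.07 without control replicate 1 and -0.19 without MR replicate 4. Methyltransferase genes were lower in 19 of 24 (median -0.12, camera adjusted p = 0.0108, adjusted p = 0.682 with an estimated correlation), with Prmt5 (-0.21) and Suv39h2 (-0.36) lower and Ezh1 (0.33) higher, and the call was lost without control replicate 2 (camera adjusted p = 0.152, median -0.04) or MR replicate 1 (0.532, median -0.02). Lipid and sterol synthesis genes were lower in 22 of 24 (median -0.19, camera adjusted p = 0.0226, adjusted p = 0.832 with an estimated correlation), with Fasn (-0.37) and Hmgcs1 (-0.47), and the call was lost without control replicate 1 (camera adjusted p = 0.371, median -0.11), control replicate 3 (0.809, median 0.01), MR replicate 2 (0.722, median -0.07) or MR replicate 4 (0.405). Their median was -0.31 without control replicate 2, -0.37 without control replicate 4 and -0.51 without MR replicate 1. TCA cycle genes were lower in 17 of 21 (median -0.08, camera adjusted p = 0.0195, adjusted p = 0.754 with an estimated correlation), with Ogdh, Suclg1 and Dlat at -0.15, -0.15 and -0.11, and the call was lost without control replicate 1, 3 or 4 (camera adjusted p = 0.450, 0.0708 and 0.113) or MR replicate 4 (0.139). The TCA cycle median was -0.03 without control replicate 1. Nuclear OXPHOS genes were lower in 59 of 72 (median -0.06, camera adjusted p = 0.0304, adjusted p = 0.832 with an estimated correlation), with Cox5b (-0.19), Atp5mpl (-0.27) and Atp5j (-0.18), were higher without control replicate 1 (camera adjusted p = 0.0232, median 0.04), and lost their call without control replicate 4 (0.104) or MR replicate 4 (0.539, median -0.02). Their median was -0.11 without control replicate 2, -0.09 without control replicate 3 and -0.08 without MR replicate 1. In these 6 lists 0 members passed edgeR over all genes or adjusted over the list alone. After the length correction, chosen after seeing the data, BPD6 medians were -0.07 (methyltransferase), -0.07 (OXPHOS) and 0.10 (ribosomal protein). Relative expression in BPD6 control replicate 1 had a Spearman correlation with transcript length of -0.388. In the other BPD6 control libraries it was 0.112 to 0.278.

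Muscle genes varied widely between single BPD6 libraries. They were lower in 12 of 12 members with MR (median -0.42, camera adjusted p = 0.00250, adjusted p = 0.754 with an estimated correlation), 0 past edgeR in either count, but Myh4, a fast muscle myosin gene, was 1386 CPM in control replicate 4 and 721 CPM in MR replicate 2, and 3.20 to 157 CPM in the others. The median was -0.64, -0.82 and 1.13 without control replicates 2, 3 and 4 and 0.14, -4.39 and 0.15 without MR replicates 1, 2 and 4, and the call was lost without control replicate 4 (camera adjusted p = 0.116), MR replicate 1 (0.107) or MR replicate 4 (0.482). Pvalb (-0.62 ± 1.41) and Mb (-0.59 ± 1.28) varied alike. Keratinocyte genes did not pass (median 2.40, camera adjusted p = 0.333), with Krt5 at 129 CPM in control replicate 3 and 360 CPM in MR replicate 1 and at most 1.37 CPM in the other libraries. Melanocytic genes were higher in 6 of 6 tested (median 0.25) and did not pass (camera adjusted p = 0.0859), and MHC class II genes did not (median -0.02, camera adjusted p = 0.886). Methionine and one-carbon genes did not pass (median -0.10, camera adjusted p = 0.0591). The 18 lists that did not pass had camera adjusted p of 0.0591 to 0.945.

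**Figure D3:**
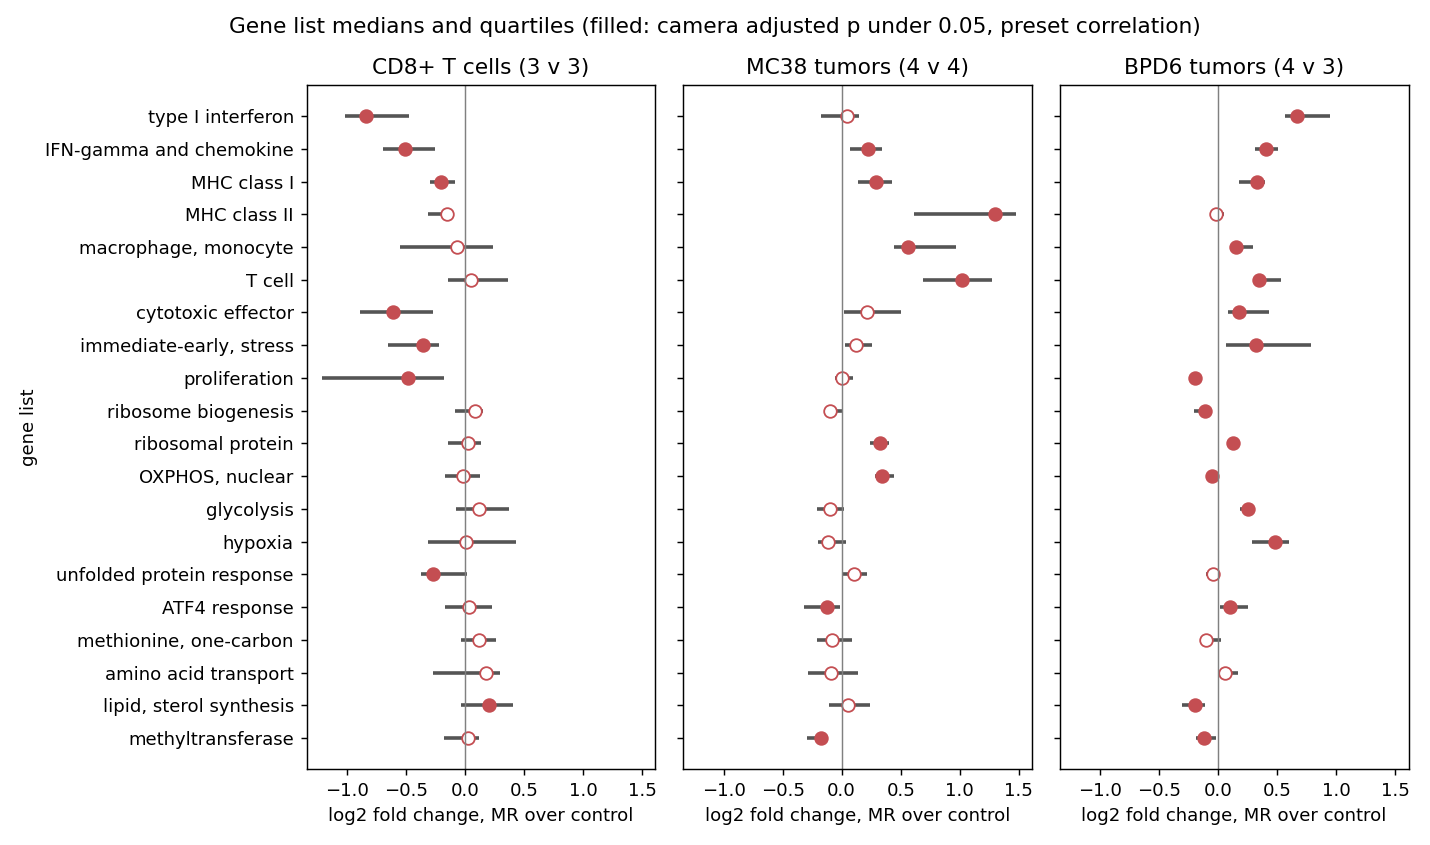
Median log2 fold change of MR over control (points) and quartiles (bars) of the members of 20 gene lists, in CD8+ T cells, MC38 tumors and BPD6 tumors. Filled points mark camera adjusted p under 0.05 at the preset correlation, all of which were lost with an estimated correlation. The type I interferon median is -0.84 in CD8+ T cells, 0.04 in MC38 and 0.66 in BPD6.

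Set side by side in the tumor models, the median difference of the MR response (MC38 minus BPD6) was 0.41 for nuclear OXPHOS genes, -0.66 for type I interferon genes, -0.64 for hypoxia genes and 1.39 for MHC class II genes. After the length correction, chosen after seeing the data, the OXPHOS medians were 0.13 in MC38 and -0.07 in BPD6. Without MC38 MR replicate 1 the OXPHOS difference was 0.25, and without MC38 MR replicate 3 the MHC class II difference was 0.80. The type I interferon difference was -0.43 without BPD6 control replicate 4 and -0.39 without BPD6 MR replicate 1. That of hypoxia genes was -0.97 and -0.42 without BPD6 control replicates 3 and 4 and -0.31 without BPD6 MR replicate 1. The interaction of model and diet was tested over 14257 genes, and edgeR called 0, with 742 at an unadjusted p under 0.05, DESeq2 7 and limma-voom 0. The 742 genes are close to the 5% of tested genes that chance gives. The count at an unadjusted p under 0.05 was 1263 without MC38 MR replicate 4 and 473 without MC38 control replicate 1. Of 39 lists, camera called 12 (8 higher and 4 lower in MC38 than in BPD6), adjusted p 4.85e-23 for OXPHOS, 1.14e-13 for type I interferon, 2.52e-05 for hypoxia and 0.000893 for MHC class II. All 12 were lost with an estimated correlation (adjusted p = 0.776 to 0.975 with an estimated correlation).

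Since edgeR called 0 genes in MC38 and 0 in BPD6, calls could not be compared between the tumor models. At an unadjusted p under 0.05 in each, 37 of 13133 genes tested in both pointed the same way and 5 opposite ways: 19 were higher, against 10.6 expected from independent lists, and 18 lower, against 7.03. Those of lowest p were chosen after their values were seen: Cpq (0.74 in MC38, 0.38 in BPD6), Cxcr4, a chemokine receptor gene (1.04, 0.37), the quiescence factor gene Klf2 (0.62, 0.53), Hsd11b1, which activates glucocorticoids (1.11, 0.98), and the glucocorticoid receptor target Tsc22d3 (0.40, 0.37). Across genes, which are not independent replicates, the fold changes of both models correlated weakly (Pearson 0.149, Spearman 0.158), and 55.8% had the same sign. Fold changes also fell with transcript length in both models (Spearman -0.43 in MC38, -0.14 in BPD6). How much of the overlap and correlation comes from this shared trend was not tested. The models share no control libraries.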

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

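The tests of handling stress, and of adjacent fat for the OXPHOS pattern, were chosen only after their results were seen, and the corrections for transcript length and for marker scores were added after the data had been seen. An explanation was set aside where the median met the bound set against it and the quartile of the members lay beyond the bound set for it. This use of the quartile was added after the corrected values were known.

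In CD8+ T cells, the cold-inducible genes Cirbp and Rbm3 were higher and heat shock chaperones lower with MR. The values argue against B cell and macrophage RNA carried over into the control libraries as the whole cause. With the B cell and macrophage score as a covariate the chaperone median was -0.729, against -0.767 without it, and 11 of 19 chaperones passed edgeR in both fits. The score holds no dendritic, NK or red cell list (medians -0.61, -0.55 and -1.26), so carry-over of those cells was not tested. B cell markers were themselves lower with MR, so score and diet are hard to separate in this fit. Their median also rested on 1 library (-0.39 without control replicate 3). A difference in the time of day of collection cannot be told apart from diet, since 4 of 10 clock genes other than Per2 had an unadjusted p under 0.05 and collection times are not in the labels. More handling stress in the control cells may also account for the pattern, as immediate-early genes without heat shock genes had a median of -0.319, between the bounds set for and against it. A response of the cells to diet is the biological explanation and stays open beside these.

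In MC38 tumors, OXPHOS and ribosomal protein genes were higher and methyltransferase genes lower with MR. More immune cells in the MR tumors met the bound set against it, since with the macrophage score as a covariate the OXPHOS median was 0.551 (lower quartile 0.407), above the 0.346 without it. This speaks only against macrophages as the whole cause, because the score holds no other immune cells. Macrophage genes were themselves higher with MR, so score and diet are hard to separate in this fit. The pattern is consistent with a transcript length bias between libraries, because a length correction brought the OXPHOS median from 0.346 to 0.128, the ribosomal protein median from 0.322 to 0.101 and the methyltransferase median from -0.172 to -0.0607. Adjacent fat in the tumor piece cannot be told apart from diet, since with the adipocyte score as a covariate these medians were 0.202, 0.133 and -0.141, and 690 genes had an unadjusted edgeR p under 0.05, beside 1981 without it and 1415 with the length correction. Such a trend with length can arise in RNA handling or library preparation, and whether diet contributes to it was not tested.

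Macrophage and MHC class II genes were higher with MR in MC38 tumors, with a median of 0.785. Lymphoid tissue in MR replicate 3 was argued against as the whole cause, since without that library the median was 0.665 (lower quartile 0.476), and both lists kept their camera call at the preset correlation with each library left out (highest adjusted p = 0.000256 and 0.000564). By camera with an estimated correlation both calls were lost (adjusted p = 0.682 for each list). Adjacent fat in the tumor piece could account for part of it and cannot be told apart from diet, since with the adipocyte score as a covariate the median was 0.586 (lower quartile 0.466), just under the share set for setting it aside. With the length correction the median was 0.749 (lower quartile 0.418). A larger share of macrophages in tumors of MR mice is the biological explanation, untested here.

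Splits of the libraries other than by diet were fitted in the same way. For CD8+ T cells the 10 splits are too few for a share under 0.05: the real split called 174 genes and the highest other 0, the real split being the 1 with as many, and 14 lists against a highest other of 15, with 2 splits at or above the real. The real split called 0 genes in MC38, BPD6 and the interaction, so all 35, 35 and 60 splits necessarily called as many, which tests nothing. For MC38 the highest other called 260 genes. That split set control replicate 4 with MR replicates 2, 3 and 4 against the rest, so it is the diet split with control replicate 4 and MR replicate 1 swapped. Whether it reflects diet, a structure of the samples or the extreme of many splits was not tested. For lists, 26 of 35 MC38 splits called at least the real 13 (highest other 22), so chance was not excluded. For BPD6 the highest other called 69, for control replicate 3 with MR replicates 1 and 4, which is the diet split with control replicate 3 and MR replicate 2 swapped. These libraries lay at 41.5, 53.5 and 14.9 on the first principal component, the main axis of variation between BPD6 libraries (45.9% of variance). All other BPD6 libraries lay at -52.2 to -14.0. This split therefore follows the main axis of variation, which does not separate the diets, and what causes that axis was not tested. Of the BPD6 splits, 5 of 35 called at least the real 23 lists, adjusted within the comparison (highest other 25), so chance was not excluded. For the interaction the highest other of those drawn called 159, and its cause was not tested.

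Of 308 values tested in groups of 4, 18 had a lowest or highest library whose gap to the nearest, as a share of the group's range, exceeded Dixon's 95% critical value. Chance gives about 1 in 20. Among BPD6 control libraries, replicate 4 was lowest in MHC class I genes (share 0.894), cytotoxic genes (0.975), B2m (0.892) and H2-D1 (0.885) and highest in Myh4 (0.903). Replicate 3 was highest in keratinocyte genes (0.900), replicate 2 in Adgre1 (0.888) and replicate 1 in Blnk (0.849) and Dkc1 (0.870). Among MC38 control libraries, replicate 4 was highest in keratinocyte genes (0.911), Cd209a (0.922) and H2-Eb1 (0.882), and replicate 3 lowest in Psmb8 (0.841). Among MC38 MR libraries, replicate 1 was highest in Atp5mpl (0.862) and Rpl39 (0.834), replicate 3 in H2-DMb2 (0.960), and replicate 4 in Capg (0.981) and Sesn2 (0.834).

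At the preset correlation, camera on the interaction called 12 lists as differing between the tumor models in their MR response, and none held with an estimated correlation. The adjusted p was 4.85e-23 for OXPHOS, 1.14e-13 for type I interferon, 1.59e-05 for both ATF4 target and proliferation genes, 1.84e-05 for ribosomal protein, 2.52e-05 for hypoxia and 0.000117 for glycolysis genes. It was 0.000893 for MHC class II, 0.00166 for macrophage, 0.0128 for both TCA cycle and unfolded protein response, and 0.0328 for fatty acid oxidation genes. By camera with an estimated correlation their adjusted p was 0.776 to 0.975. The ribosomal protein difference went from 0.22 to 0.0077 without MC38 MR replicate 1, and that of proliferation genes from 0.23 to 0.12 without BPD6 control replicate 1. For glycolysis genes it was -0.33, but -0.08 without BPD6 MR replicate 1 and -0.54 without BPD6 control replicate 3. For ATF4 target genes it was -0.21, but -0.08 without BPD6 MR replicate 4 and -0.35 without BPD6 MR replicate 1.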

How the results depend on the processing

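The fits with marker scores or transcript length, the fit of genes with the same transcript in both tumor tables, and the joint fit at an unadjusted p were chosen only after the data were seen. In CD8+ T cells the 174 genes called became 96 with a minimum absolute log2 fold change of 1, 559 with DESeq2, 74 with the replicate number as a block and 273 with the B cell and macrophage score as a covariate, and 7 (without MR replicate 1) to 290 (without MR replicate 2) with a library left out. Fewer samples are part of the lower counts, and otherwise the cause was not tested. The count was 134 to 207 with median-of-ratios size factors, no filter, limma-voom or the length correction. DESeq2 called 406 genes in MC38, 1 in BPD6 and 7 in the interaction, where edgeR called 0 under each alternative run. Genes pointing the same way in both tumor models at an unadjusted edgeR p under 0.05 numbered 37 (10.6 higher and 7.03 lower expected) and, in the joint fit, 55 (16.4 and 10.9 expected). The 48 list calls became 0 with an estimated correlation and 1 with fry, and 42 to 60 with a library left out.

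Nothing in the labels says whether replicate numbers pair the libraries. Correlations of same-number libraries, across genes as deviations from the group mean, were 0.042, -0.179 and -0.154 in CD8+ T cells. In MC38 they were -0.026, -0.284, -0.107 and 0.383. With so few libraries per group these values cannot settle whether a pairing exists. The replicate block was run for CD8+ T cells and MC38 (0 genes called) all the same. It was not run for BPD6 or the interaction, because the BPD6 MR columns carry other numbers than their labels.

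Of 23 named CD8 genes past the test, 3 were called and none turned with DESeq2, median-of-ratios size factors, no filter, limma-voom, the block and each library left out, and single genes were not taken from the length or score corrections. Among named genes not past it, 1 in CD8, 5 in MC38 and 12 in BPD6 turned under some of these, and the cause was not tested. With the block, Pdcd1 in CD8+ T cells was 0.0565 and Atf4 in MC38 -0.0625. With limma-voom, Atf4 in MC38 was -0.0619, and in BPD6 Asns was -0.0115, Slc7a5 -0.0177 and Myc 0.0067. With median-of-ratios size factors Myc in BPD6 was 0.00, and with no filter 0.002. With a library left out, log2 fold changes ranged from -0.53 to 0.77 for Pdcd1 in CD8+ T cells. In MC38 the ranges were -0.25 to 0.047 (Asns), -0.26 to 0.18 (Atf4), -0.21 to 0.0236 (Cd274), -0.34 to 0.49 (Ifng) and -0.42 to 0.0346 (Myc). In BPD6 they were -0.22 to 0.21 (Asns), -0.038 to 0.18 (Atf4), -0.0003 to 0.98 (Cd3d), -0.24 to 0.63 (Gzmb), -0.15 to 0.11 (Mat2a), -3.57 to 0.31 (Mb), -0.25 to 0.17 (Myc), -4.97 to 1.47 (Myh4), -0.69 to 0.18 (Pdcd1), -0.16 to 0.44 (Prf1), -4.20 to 0.64 (Pvalb) and -0.21 to 0.19 (Slc7a5).

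With a library left out, 9 of 14 lists kept their call in CD8+ T cells, 8 of 13 in MC38 and 7 of 21 in BPD6. In BPD6, 4 lists turned by the direction of camera for 1 library each, and the medians of T cell (-0.08) and cytotoxic genes (-0.15) turned without MR replicate 1 and that of muscle genes without control replicate 4 (1.13), MR replicate 1 (0.14) or MR replicate 4 (0.15). For the 4 lists the camera adjusted p ranged from 6.68e-11 to 0.574 for ATF4 targets (turned without MR replicate 4), 1.69e-07 to 0.957 for interferon gamma genes (without control replicate 4), 2.77e-07 to 0.539 for OXPHOS (without control replicate 1, 0.0232) and 1.08e-10 to 0.809 for lipid and sterol synthesis (without control replicate 3). Simulated 1.5-fold changes were recovered in 20% (CD8), 14% (MC38) and 8% (BPD6) of cases, so changes of that size are mostly beyond these libraries.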

Other observations

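The tests of glucocorticoid targets and of the Xist to Ddx3y ratio below were chosen only after the result was seen, and the lists of this part were written after the data had been seen. Heat shock chaperone genes, which aid protein folding, had a median of -0.767 in CD8+ T cells with MR, and 11 of 19 fell past edgeR. They were at 0.02 in MC38 and -0.13 in BPD6 tumors. Cirbp had a log2 fold change of 0.44 in MC38 and 0.42 in BPD6, not past edgeR in either.

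Raised glucocorticoid signalling under MR in all 3 materials may be considered, since Tsc22d3 and Hsd11b1 were higher in both tumor models and Fkbp5 in CD8+ T cells, although Tsc22d3 stood at 0.09 in CD8+ T cells and Fkbp5 at -0.08 in BPD6. A list of glucocorticoid target genes was up in 1 of 3 comparisons, MC38, by the rotation test fry of limma, but it held Tsc22d3, Fkbp5, Sgk1 and Cebpd, which had been seen to be higher before it was written. Without these 4, glucocorticoid target genes were again up in 1 of 3 comparisons, MC38 (median 0.25, unadjusted p = 0.0192 in limma's fry). In limma's fry the unadjusted p of the shortened list was 0.124 in BPD6 (median 0.24) and 0.487 in CD8+ T cells (median -0.17). The wording of what would speak against this hypothesis was changed after the result was known, and the hypothesis stays open.

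A change in the share of host RNA in BPD6 tumors could alter many genes alike. The log2 ratio of Xist to Ddx3y, which moves with that share only if host and tumor cells differ in sex, was -0.54 ± 0.56 in control (SD, n = 4) and -0.53 ± 0.19 in MR tumors (n = 3). It differed by 0.012 (95% interval -0.876 to 0.9, exact permutation test, two-sided p = 0.971, smallest possible 0.0286). If the sexes differ, this argues only against differences in the log2 ratio outside that interval. Differences within it, which could still alter many genes, are not excluded. The sexes are not in the labels.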
